A study of Mus musculus with 12 samples.

How the data were processed

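RNA from mature cDC1 and cDC2 sorted from mouse spleen was measured on 12 GeneChip gene arrays, with 2 biological replicates for each of 6 groups: WT, Flt3 KO and Flt3L KO, each for both cell types. Groups were taken from the sample labels. The labels do not say whether a sample pooled mice, or whether equal replicate numbers of different cell types share animals. The values are intensities on a linear scale, 1 per probe set and array, used as deposited; the method of summarisation and normalization is not given in the sources used here. The median distance of a sorted log2 value from the mean of its rank was 0.0125, so the arrays had close to the same distribution. Detection calls were not used here. Fold changes of dim genes are imprecise, and may be understated where background remains in the values of both groups.

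The value table held 30177 probe sets on 12 arrays. Probe sets with exactly 1 gene symbol (21789) were kept for the gene tests; 1621 with several symbols and 6767 absent from the probe table were tested apart. Symbols were checked by Entrez ID against a RefSeq gene table for 21698 probe sets, and 0 were changed; that table was otherwise used only for the order of genes. For the 999 genes with more than 1 probe set, the probe set with the highest mean was used. Of 19938 genes with a value, the lowest share of 0.25 by mean log2 intensity was left out, except Flt3 and Flt3l, leaving 14953 genes with a mean log2 value of at least 4.78.

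Log2 intensities of the 12 arrays were fitted with 1 mean per group in limma 3.58.1 under R 4.3.3, with statmod 1.5.0 and 6 residual degrees of freedom. Contrasts compared cDC1 with cDC2 in each genotype, each knockout with WT and the knockouts with each other in each cell type, the averages of these, and the difference of each knockout effect between cDC2 and cDC1. P-values were adjusted by the Benjamini-Hochberg method within a comparison, and genes with an adjusted p under 0.05 were called. Values are log2 differences with the standard error from limma, or folds. The median standard error was 0.0937 for comparisons within a cell type or genotype and 0.0663 for averages over cell types. It was 0.0541 for cDC1 against cDC2 averaged over genotypes and 0.133 for differences of effects.

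Fixed lists of genes (34, with 658 distinct genes, of which 590 had a value and 534 were tested) were tested with camera from limma, with a preset correlation between genes of 0.01 and again with a correlation estimated from the data. They covered cDC1, cDC2, ESAM-high, ESAM-low and pan-cDC genes, functions of dendritic cells, signalling and metabolism, and markers of other cell types. The 33 lists with at least 5 tested genes were tested, and the sex-linked list, with 3, is given gene by gene. For each list, members called among all genes and members called when adjusted over the list alone were counted.

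Genes are named by a rule. They are Flt3 and Flt3l; among called genes with all arrays of one group above those of the other, the 8 largest rises and 8 largest falls, leaving out predicted and clone-named genes, small RNA genes and segments of immunoglobulin and T cell receptor genes; of each list that passed or held a called member, up to 4 members with the smallest p; and 12 markers of cell identity. Where fewer than 5 genes passed, the 5 smallest p-values were tabulated. These choices, the lists and most alternatives were made before the data were examined. Genes called in both knockouts, or near Flt3, fall outside the rule and were named after their values were seen.

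The method was tested on simulated data with independent noise, each gene having 1 spread pooled over all groups. Changes of 0.5 on the log2 scale were recovered for 83.58, 85.07, 86.57 and 88.06% of 67 genes (Flt3 KO cDC1, Flt3 KO cDC2, Flt3L KO cDC1 and Flt3L KO cDC2), and changes of 1 and 2 for 100%. False calls numbered 8 of 197, 10 of 200, 11 of 202 and 5 of 197. The WT cDC1 replicates differed more than those of the other groups, so these rates may not hold for comparisons with WT cDC1. Each simulation changed 200 genes, while limma called 12 and 16 genes in Flt3 KO cDC1 and cDC2. With fewer changed genes the Benjamini-Hochberg cut-off is stricter, so changes of 0.5 may be recovered less often there. The expectation for effects sharing WT arrays came from 1000 simulated draws without any change, and the shared calls from the first 100 of them. After the data were seen, the covariance due to shared WT arrays was also estimated for each cell type as the variance across genes of the difference between its WT replicates, divided by 4.

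Alternatives were quantile normalization; no filter on dim genes; a share of 0.5 left out; a trended and robust variance prior; the mean of a gene's probe sets; only the arrays compared; the replicate number as a block; and each array left out in turn, with the lone array of a group assumed to vary like the other groups. A block of crossed replicate numbers was added after the data were seen. Splits of the arrays into other groups of the same sizes, at most 100, were fitted with cell type or genotype as a further term, keeping 2 arrays of each cell type or genotype on either side. Over-representation of called genes among the 50 tested genes on each side of a gene was tested with a one-sided Fisher exact test.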

Results

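Gene expression was measured on 12 GeneChip arrays, each hybridised with RNA from conventional dendritic cells sorted from mouse spleen. The cells were mature cDC1 and cDC2, the 2 main branches of conventional dendritic cells, taken at steady state from wild-type (WT) mice, Flt3 knockout (KO) mice and Flt3L KO mice. Flt3 encodes a receptor tyrosine kinase that supports dendritic cell development, and Flt3l encodes its ligand. Each of the 6 groups of genotype and cell type had 2 arrays, described by the labels as biological replicates. The labels do not say how many mice were used per array, so p-values measure the spread between these arrays. With 1 probe set kept per gene and dim genes left out, 14953 genes were tested, and the number of arrays limits the precision of every value. The median standard error (SE) of a log2 difference between groups was 0.09. The median intensity of an array ranged from 59 to 63. Replicate 1 of WT cDC1 stood apart from the other arrays: its lower quartile of intensity was 25.7, against 23.3 to 24.3 on the others. The standard deviation (SD) of the log2 difference between the WT cDC1 replicates was 0.21, against 0.13 to 0.15 in the other groups.

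The targeted genes were examined first, as a check of the genotype labels. Flt3 fell in both cell types of Flt3 KO mice. Its mean intensity was 2299 ± 47.6 (SD, n = 2) in WT cDC1 and 364 ± 9.58 (SD, n = 2) in Flt3 KO cDC1, a difference of 6.32-fold with an adjusted p of 5.3e-10. In cDC2 the means were 1779 ± 53.2 (SD, n = 2) in WT and 361 ± 14.7 (SD, n = 2) in Flt3 KO, a difference of 4.93-fold with an adjusted p of 3.2e-09. The Flt3L KO groups had Flt3 intensities of 2441 ± 20.6 (SD, n = 2) in cDC1 and 1642 ± 6.15 (SD, n = 2) in cDC2, and neither differed from WT past the threshold (adjusted p = 0.572 and 0.502). Flt3l, measured by 1 probe set, had an intensity of 113 ± 0.611 (SD, n = 2) in WT cDC1 and 124 ± 6.68 (SD, n = 2) in Flt3L KO cDC1, with an adjusted p of 0.403. In cDC2 it fell by 0.37 ± 0.08 (SE) on the log2 scale, from 147 ± 3.24 (SD, n = 2) to 113 ± 6.27 (SD, n = 2), with an adjusted p of 0.027. The part of Flt3l deleted in these mice is not given in the sources used here, so the probe set does not check the Flt3L KO labels.

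**Figure D1:**
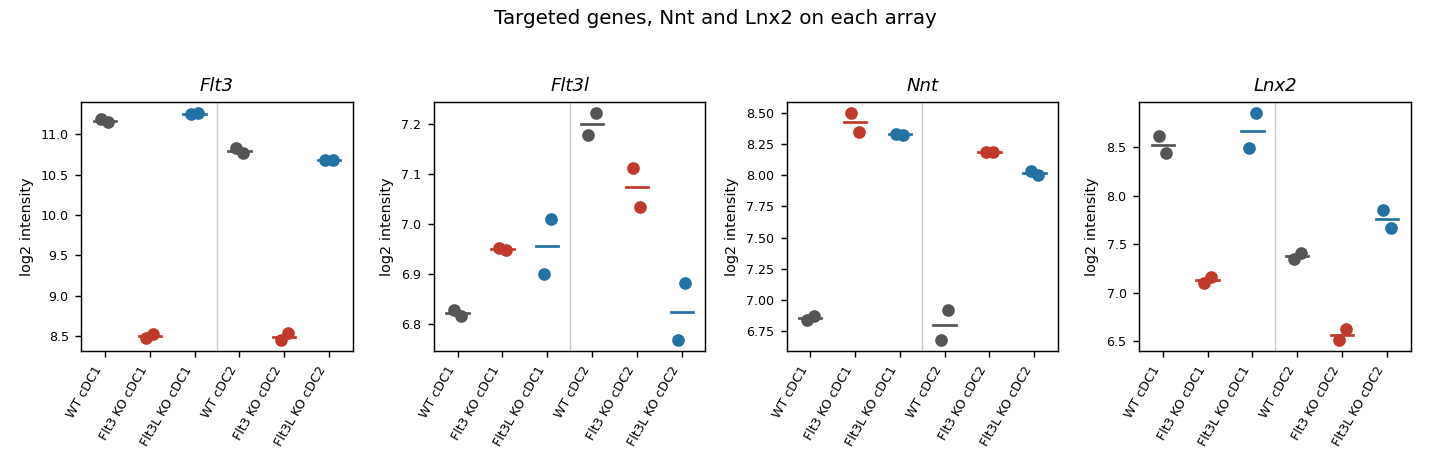
Log2 intensity of Flt3, Flt3l, Nnt and Lnx2 on each of the 12 arrays, by group; points are arrays and short lines are group means of 2 arrays, with a separate vertical axis for each gene. Flt3 and Lnx2 lie lower on the Flt3 KO arrays, and Nnt lies higher on the arrays of both knockouts than on the WT arrays.

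The comparison of WT cDC1 with WT cDC2 asks how the branches differ before either gene is removed. Genes that define cDC1 were higher in cDC1 by large factors: Xcr1, a chemokine receptor, was 43.4-fold higher, Clec9a, a receptor for dead-cell material, was higher by 4.18 ± 0.13 (SE) on the log2 scale, and the transcription factor Irf8 was 10.4-fold higher. Itgae was higher by 3.75 ± 0.12 (SE) and Cd8a was 14.4-fold higher. Batf3, a transcription factor needed for cDC1, was higher by 0.65 ± 0.08 (SE) on the log2 scale. Genes that define cDC2 were lower in cDC1: Sirpa was 34.3-fold lower, the lectin Clec4a4 about 29.3-fold lower and the transcription factor Irf4 9.89-fold lower. Esam changed by -1.02 ± 0.10 (SE) on the log2 scale. Zbtb46, a transcription factor shared by both branches, changed by -0.15 ± 0.12 (SE; adjusted p = 0.358). Other large differences were P3h2, 63.6-fold higher, Gpr141b, 57.5-fold higher, and Mmp12, 47.4-fold lower in cDC1. Plpp1, Ifi205, P2ry14, Rab7b and Tlr3 were 38.6-, 36.5-, 35.2-, 24.6- and 22.9-fold higher, and Tlr7, Tgm2, Dscam, Cybb and Adgre1 were 36.2-, 30.4-, 29.3-, 23.6- and 23.3-fold lower. Clec4a4 had a mean intensity of 12.3 in WT cDC1, under the lower quartiles of the arrays. Tlr7 and Clec4a1 in WT cDC1 and Plpp1 in WT cDC2 also lay under them. The folds of these genes are therefore imprecise and may be understated.

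Across all genes, limma called 5896 genes between WT cDC1 and WT cDC2 at adjusted p 0.05, 3145 higher and 2751 lower in cDC1, and 969 of them differed by more than 2-fold. Of the fixed lists, 28 of 29 tested cDC1 genes were higher and 0 lower, with the count adjusted over the list alone also 28. Of 28 tested cDC2 genes, 22 were lower and 4 higher, and the counts adjusted over the list alone were also 22 and 4. Of 17 ESAM-low cDC2 genes 13 were lower and 2 higher, including Clec4a1, about 18.8-fold lower, and Cd209a, with a log2 difference of -3.70. Of 9 genes of ESAM-high cDC2 that depend on Notch2, 6 were lower, including Cd4, 7.66-fold lower. Adjusted over the list alone, the counts of the ESAM-low and Notch2-dependent lists did not move. The list of cytokine and growth factor receptors fell, with 16 of 27 lower and 1 higher (17 and 1 adjusted over the list alone), led by Csf1r, the receptor of macrophage colony-stimulating factor, 11.6-fold lower, and Il21r, 8.27-fold lower. These 5 lists kept their calls with an estimated correlation (adjusted p = 0.00396, 0.0027, 0.00586, 0.0229 and 0.013, for cDC1, cDC2, ESAM-low, Notch2-dependent and receptor genes). Among lists of function, 14 of 17 genes of MHC class I presentation were higher and 1 lower (15 and 1 adjusted over the list alone), such as the peptide transporter subunit Tap2, 2.40-fold higher, while the list's adjusted p = 0.108 with an estimated correlation. For MHC class II presentation, 7 of 13 were lower, and 7 lower and 1 higher adjusted over the list alone; the protease gene Lgmn was 3.98-fold lower, and the list had an adjusted p = 0.109 with an estimated correlation. Of 26 interferon-stimulated genes 17 were lower and 3 higher (18 and 3 adjusted over the list alone), such as Rtp4, 11.9-fold lower, with an adjusted p = 0.297 with an estimated correlation. Of 31 genes of oxidative phosphorylation, 23 were higher and 0 lower (24 adjusted over the list alone), with an adjusted p = 0.297 with an estimated correlation. Lists of dendritic cell transcription factors (17 of 35 lower, 5 higher; 18 and 5 adjusted over the list alone) and Toll-like receptors (8 of 12 lower, 2 higher; 8 and 4 adjusted over the list alone) fell, with adjusted p = 0.0791 and 0.212 with an estimated correlation. The maturation list (13 of 25 lower, 6 higher), the immediate early list (10 of 26 lower, 3 higher) and the glycolysis list (9 of 17 higher, 3 lower) also passed, and had adjusted p = 0.55, 0.297 and 0.159 with an estimated correlation; adjusted over the list alone their counts were 13 and 7, 10 and 3, and 9 and 3.

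Markers of other cell types were examined beside these lists. The monocyte, macrophage and NK cell lists were lower in cDC1, with 6 of 13, 8 of 18 and 5 of 9 members lower and 1, 2 and 2 higher; adjusted over the list alone the first count became 7 and the others did not move. Their adjusted p was 0.153, 0.142 and 0.192 with an estimated correlation. Members that led them are also genes of cDC2, such as Itgam, 15.9-fold lower, and the adhesion receptor gene Adgre1. The lists for pDC, B cells, T cells, neutrophils, erythroid cells, platelets, plasma cells, basophils, stromal cells and progenitors did not pass (adjusted p 0.711, 0.356, 0.736, 0.07, 0.853, 0.998, 0.717, 0.855, 0.356 and 0.753). Neither did the pan-cDC, cell cycle, receptor tyrosine kinase, BCL2 family, cholesterol and chemokine lists (adjusted p 0.356, 0.806, 0.173, 0.923, 0.736 and 0.639). The 3 tested Y-linked genes were lower in cDC1 than in cDC2: Uty 1.94-fold, Eif2s3y 1.66-fold and Kdm5d 1.35-fold, and Xist had a mean intensity between 14.8 and 17.2 in the 6 groups. In all, 17 of 33 lists passed with the preset correlation and 5 with an estimated one.

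The cell type difference was then compared across genotypes, to ask how far it was kept without the receptor or its ligand. The arrays hold only cells sorted as cDC1 or cDC2, so the sort itself kept part of the difference. Of the 969 genes that differed by more than 2-fold in WT, 966 were called in the same direction in Flt3 KO and 961 in Flt3L KO. Xcr1 had an intensity of 2878 ± 112 (SD, n = 2) in WT cDC1, 2953 ± 95.8 (SD, n = 2) in Flt3 KO cDC1 and 2445 ± 33.9 (SD, n = 2) in Flt3L KO cDC1. Across all tested genes, which are not independent replicates, the correlation of the cDC1 to cDC2 log2 differences with those in WT was 0.948 for Flt3 KO and 0.925 for Flt3L KO. Over the 969 genes, the slope on the WT difference was 0.96 in Flt3 KO and 0.91 in Flt3L KO. These genes were chosen by the size of their WT difference, which by itself can draw the slope below 1. The number of genes called between cDC1 and cDC2 was 5305 in Flt3 KO (2859 higher and 2446 lower in cDC1), 5209 in Flt3L KO (2831 and 2378) and 7711 averaged over genotypes (4195 and 3516). Fixed lists that passed numbered 16, 15 and 16, and 5, 6 and 6 with an estimated correlation.

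In Flt3 KO cDC1, Nnt, a mitochondrial transhydrogenase, rose 2.97-fold (adjusted p = 2.3e-06), and the lectin gene Cd209a rose 1.89-fold (adjusted p = 0.0165). Gpr141, Tmem176a, Adam11, Rfc3, Lpp and the Fc receptor subunit gene Fcer1g rose 1.71-, 1.60-, 1.56-, 1.55-, 1.53- and 1.51-fold. Besides Flt3, Lnx2 fell by 1.40 ± 0.12 (SE) on the log2 scale (adjusted p = 0.00015), the heat shock gene Hsph1 fell by 0.74 ± 0.12 (SE), and Polr1d, a subunit of RNA polymerases I and III, fell by 0.65 ± 0.08 (SE). Lnx2, Polr1d, Hsph1 and Rfc3 lie near Flt3 in the gene order. These 12 genes, 8 higher and 4 lower, were all that passed, against 1873 at an unadjusted p under 0.05, where 748 are expected by chance.

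Among the fixed lists in Flt3 KO cDC1, the maturation list rose, with 0 of 25 members past the threshold and 8 higher adjusted over the list alone; Anxa3 and Socs2, an inhibitor of cytokine signalling, led it with log2 changes of 0.64 ± 0.12 and 0.56 ± 0.11 (SE; adjusted p = 0.0599 and 0.117). The cholesterol biosynthesis list rose with 0 of 20 called and 4 higher adjusted over the list alone; Nsdhl and Hmgcs1 had changes of 0.44 ± 0.09 and 0.38 ± 0.09 (SE; adjusted p = 0.155 and 0.205). The maturation and cholesterol lists had an adjusted p = 0.285 and 0.27 with an estimated correlation. Of 28 cDC2 genes 2 rose (4 higher and 1 lower adjusted over the list alone), and of 17 ESAM-low cDC2 genes 2 rose (4 adjusted over the list alone), in both cases Cd209a and Tmem176a; these lists rose, with an adjusted p = 0.173 and 0.215 with an estimated correlation. The cytokine receptor list rose with 0 of 27 members called and 1 higher adjusted over the list alone, Il21r (0.39 ± 0.09 (SE), adjusted p = 0.174). The immediate early and heat shock list rose although its called member, Hsph1, fell, with 3 higher and 1 lower of 26 adjusted over the list alone. The receptor and immediate early lists had an adjusted p = 0.245 and 0.433 with an estimated correlation. The stem and progenitor list, which holds Flt3, fell with 1 of 16 called, and its adjusted p = 0.433 with an estimated correlation. Without Flt3 its adjusted p was 0.372 with the preset correlation and 0.662 with an estimated one. The pan-cDC list, which also holds Flt3, had an adjusted p of 0.26; without Flt3 it was higher with an adjusted p of 0.0246, and then its adjusted p = 0.268 with an estimated correlation.

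Precision was low in this comparison: the count of 12 became 4, 1132, 3 and 5 without replicates 1 and 2 of WT cDC1 and replicates 1 and 2 of Flt3 KO cDC1, and Flt3, Nnt and Lnx2 kept their calls each time. The count was 35 with a trended, robust variance prior, 22 with a share of 0.5 of the dimmest genes left out, 20 with crossed replicate numbers, 7 with the mean of a gene's probe sets and 3 when only these arrays were fitted.

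In Flt3 KO cDC2, C1qa, a chain of complement component C1q, rose 2.19-fold (adjusted p = 0.0107), and Lyz2, which encodes lysozyme, rose 1.67-fold (adjusted p = 0.00757). Ms4a7 and the lipid-binding gene Fabp5 rose 1.71- and 1.63-fold, and the adhesion molecule Vcam1 1.43-fold. Nnt rose 2.62-fold (adjusted p = 1e-05), H2-M2 1.91-fold, Enpp5 1.61-fold and Maged1 1.61-fold. Besides Flt3, the B cell scaffold gene Bank1 fell by 0.95 ± 0.15 (SE) on the log2 scale, the NK receptor gene Klra5 fell by 0.93 ± 0.11 (SE) and Lnx2 fell by 0.81 ± 0.12 (SE). In all, 16 genes passed, 12 higher and 4 lower, against 1089 at an unadjusted p under 0.05.

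The ESAM-low cDC2 list rose in Flt3 KO cDC2: 1 of 17 members was called, Lyz2, and 9 were higher adjusted over the list alone, with a median log2 change of 0.32. This was the list that kept its call with an estimated correlation (adjusted p = 0.013). Its next members, Fcgr3 and Tmem176a, had changes of 0.45 ± 0.08 and 0.43 ± 0.11 (SE; adjusted p = 0.0866 and 0.262). The macrophage list rose with 2 of 18 called, C1qa and Vcam1, and 4 higher and 1 lower adjusted over the list alone, with an adjusted p = 0.2 with an estimated correlation. The monocyte list did not pass (0 of 13 called, adjusted p = 0.481). The cDC2 list (1 of 28 higher; 8 higher and 2 lower adjusted over the list alone) and the cDC1 list (0 of 29; 9 higher and 1 lower adjusted over the list alone) rose, with an adjusted p = 0.268 and 0.432 with an estimated correlation. Irf8 and Clec9a had log2 changes of 0.48 ± 0.08 and 0.50 ± 0.13 (SE; adjusted p = 0.066 and 0.256). The maturation list rose with 0 of 25 called and 3 higher adjusted over the list alone, and the cholesterol list rose with 0 of 20 called and 0 adjusted over the list alone; each had an adjusted p = 0.432 with an estimated correlation. The interferon-stimulated list fell with 0 of 26 called and 0 adjusted over the list alone, and the cell cycle list fell with 0 of 35 called and 0 adjusted over the list alone, with an adjusted p = 0.432 and 0.648 with an estimated correlation. The median cell cycle change was -0.12, while the median difference of replicate 1 from replicate 2 of Flt3 KO cDC2 over that list was 0.28.

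The count of 16 became 6, 2, 2 and 5 without replicates 1 and 2 of WT cDC2 and replicates 1 and 2 of Flt3 KO cDC2, with Flt3 and Nnt kept each time, and was 36 with a trended, robust prior, 10 with no filter on dim genes and 9 with a share of 0.5 of the dimmest genes left out. Averages over cell types, here and below, treat the cDC1 and cDC2 arrays as independent. Their SEs would be too small if equal replicate numbers share animals and deviate together. Averaged over cell types, 38 genes passed in Flt3 KO against WT, 29 higher and 9 lower. Among them were Nnt, Flt3, Lnx2, Anxa3 at 0.63 ± 0.08 and the actin-bundling gene Fscn1 at 0.49 ± 0.09 (SE, log2). Without single arrays this count ranged from 9 (WT cDC2 replicate 2) to 219 (WT cDC1 replicate 2), and was 18, 16, 18, 13 and 14 without WT cDC2 replicate 1, Flt3 KO cDC1 replicate 1, Flt3 KO cDC2 replicate 1, Flt3 KO cDC1 replicate 2 and Flt3 KO cDC2 replicate 2.

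In Flt3L KO cDC1, Mid1, a ubiquitin ligase, rose 5.26-fold (adjusted p = 0.000492), Nnt rose 2.78-fold (adjusted p = 9.85e-06) and Adam11 rose 2.43-fold (adjusted p = 1.6e-05). AI506816, the activation marker Cd69, the kinase Plk2, Gtf3c5 and Ndrg1 rose 1.95-, 1.94-, 1.88-, 1.81- and 1.78-fold. Clec4b2, a lectin, fell by 1.78 ± 0.20 (SE) on the log2 scale, Rtn1 fell by 1.16 ± 0.09 (SE), and Dusp6, a phosphatase induced by and acting on ERK, fell by 1.12 ± 0.16 (SE). Hpgd, Adgrf5, Cd207, which encodes langerin, the chemokine Ccl3 and Fcrla fell by 1.11, 1.04, 0.97, 0.96 and 0.95. In all, 178 genes passed, 116 higher and 62 lower, against 2558 at an unadjusted p under 0.05.

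By list, the cytokine receptor genes rose in Flt3L KO cDC1, with 2 of 27 called, Il21r and Il4ra, 1.64- and 1.47-fold higher, and 3 adjusted over the list alone. The cholesterol list rose with 1 of 20 called, the synthase gene Hmgcs1, 1.45-fold higher, and 6 adjusted over the list alone. The maturation list rose with 1 of 25 called, the NF-kappaB subunit gene Relb, 1.41-fold higher, and 6 adjusted over the list alone. Their adjusted p was 0.285, 0.382 and 0.521 with an estimated correlation. The interferon-stimulated list rose with 0 of 26 called and 6 adjusted over the list alone, led by Ifi27l2a and Rsad2 at 0.66 ± 0.15 and 0.73 ± 0.16 (SE, log2; adjusted p = 0.0525 for both), and its adjusted p = 0.577 with an estimated correlation. Its median change was 0.18, while the Flt3L KO cDC1 replicates differed over it by a median of 0.26. The cDC1 list fell, with Cd36 and Tlr3 1.43- and 1.61-fold lower and Gpr33 1.48-fold higher among 29 members (4 lower and 1 higher adjusted over the list alone). The cDC2 list rose, with Cd7 1.73-fold higher and Fcrla 1.93-fold lower among 28 members (7 higher and 3 lower adjusted over the list alone). Their adjusted p was 0.509 and 0.285 with an estimated correlation. Lists that did not pass held some called members: Ier3 and Btg2 of the immediate early genes fell 1.60- and 1.31-fold, Cd180 and Tlr3 of the Toll-like receptors fell 1.55- and 1.61-fold, and Ccl3 and Ccl4 of the chemokines fell 1.94- and 1.48-fold. Called members of marker lists of other cell types, none of which passed, were the B cell marker Fcrla, given above, Timd4, a macrophage receptor for dying cells, 1.87-fold lower, Icos, 1.41-fold higher, Klrk1, 1.41-fold higher, and Cd300c, 1.34-fold lower.

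The count of 178 became 89, 606, 25 and 68 without replicates 1 and 2 of WT cDC1 and replicates 1 and 2 of Flt3L KO cDC1, and 14 of the 33 called genes named by the rule kept their calls each time. Under every setting tried 6 kept them: Mid1, Nnt, Adam11, Rtn1, Hpgd and Timd4. The count was 6 when only these arrays were fitted, 545 with a trended, robust prior, 363 with a share of 0.5 of the dimmest genes left out, 98 with no filter, 118 with the replicate number as a block and 281 with crossed numbers. Whether more genes changed than in Flt3 KO cDC1 was not tested, and the order of the counts turned without WT cDC1 replicate 2 (606 against 1132).

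In Flt3L KO cDC2, C1qa, C1qb and C1qc, the chains of C1q, rose 4.60-, 3.96- and 3.10-fold (adjusted p = 1.7e-05, 0.000178 and 0.00287), Vcam1 rose 2.27-fold (adjusted p = 1.7e-05), and Mertk, a receptor for engulfing dying cells, rose by 1.00 ± 0.08 (SE) on the log2 scale (adjusted p = 8.2e-05). Clec4e, a lectin that senses microbes, rose 4.77-fold, the Fc receptor gene Fcgr4 2.98-fold and the scavenger receptor gene Cd36 2.46-fold. Mid1 rose 3.70-fold. Kcnma1, a potassium channel gene, rose from a WT level under the lower quartiles of the arrays. Its log2 change of 4.26 ± 0.90 (SE), with an adjusted p of 0.0308 in limma, is imprecise, given its large SE and that dim level. The serpin genes Serpinb2 and Serpinb10 fell by 1.19 ± 0.21 and 1.00 ± 0.12 (SE), Cd101 fell by 1.01 ± 0.09 (SE), and Cd209a fell by 0.98 ± 0.13 (SE). Mmp9, Pnma1, Adgrl3 and Mmp12 fell by 1.08, 1.03, 0.99 and 0.97. In all, 291 genes passed, 155 higher and 136 lower, against 2185 at an unadjusted p under 0.05.

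**Figure D2:**
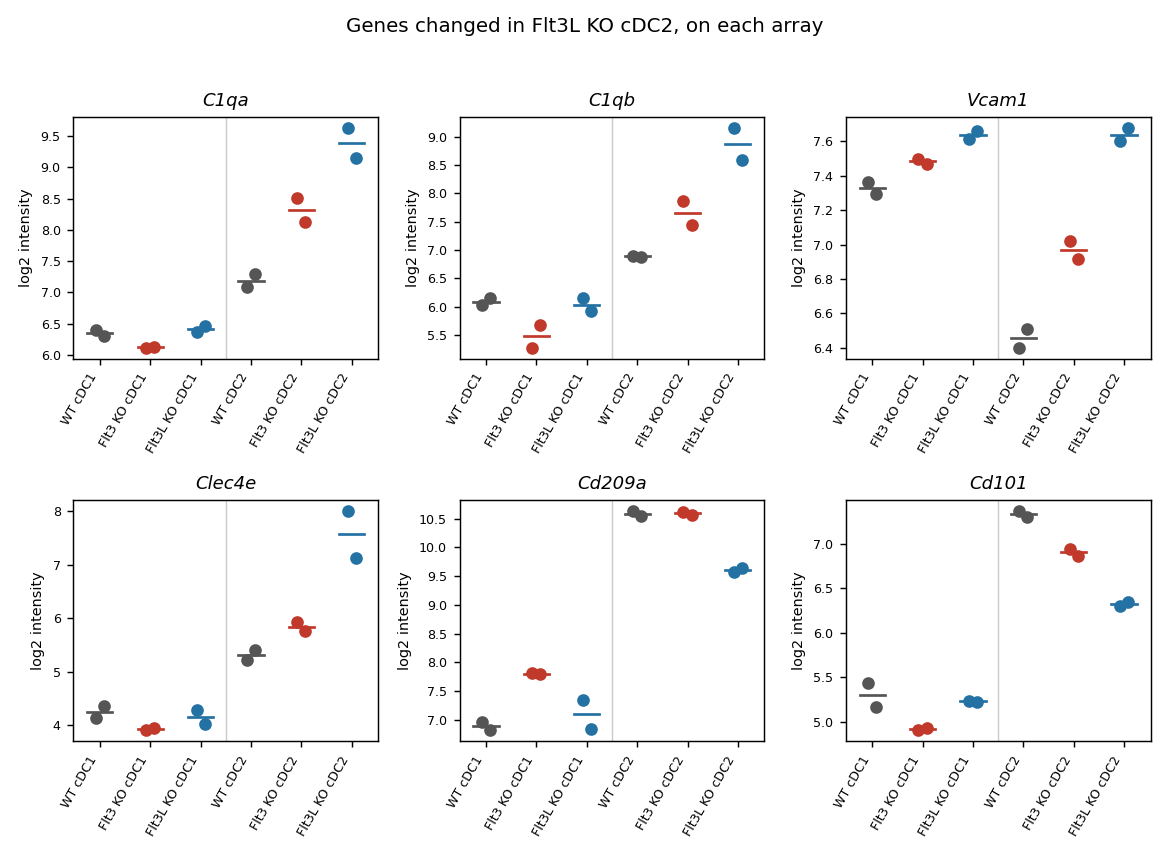
Log2 intensity of C1qa, C1qb, Vcam1, Clec4e, Cd209a and Cd101 on each of the 12 arrays, by group; points are arrays and short lines are group means of 2 arrays, with a separate vertical axis for each gene. In cDC2, C1qa, C1qb, Vcam1 and Clec4e lie higher in Flt3L KO than in WT, and Cd209a and Cd101 lie lower.

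The macrophage list rose in Flt3L KO cDC2, with 7 of 18 members higher and 2 lower (9 and 2 adjusted over the list alone) and an adjusted p = 0.0919 with an estimated correlation. The monocyte list rose, with 4 of 13 higher and 0 lower (7 and 2 adjusted over the list alone), among them Cd300e, Ace and Treml4, 2.21-, 1.84- and 1.65-fold higher; its adjusted p = 0.329 with an estimated correlation. The cell cycle list rose with 0 of 35 called and 2 adjusted over the list alone, and all 35 members had a positive change, with a median of 0.24 and an adjusted p = 0.504 with an estimated correlation. The replicates of Flt3L KO cDC2 differed over that list by a median of 0.28. The interferon-stimulated list rose with 1 of 26 called, Oasl1, 1.88-fold higher, and 2 adjusted over the list alone; its adjusted p = 0.504 with an estimated correlation, and its median change was 0.20 while the replicates of Flt3L KO cDC2 differed by a median of 0.33. The pan-cDC list fell, with 3 of 20 lower and 4 adjusted over the list alone, namely the transcription factors Bcl11a and Bcl6, and Adam19, 1.32-, 1.27- and 1.26-fold lower; its adjusted p = 0.196 with an estimated correlation. The Notch2-dependent list fell, with Clec4a4 1.62-fold lower as the called member of 9 and 2 lower adjusted over the list alone, and the immediate early list fell, with Egr3, Btg2 and Egr2 1.51-, 1.44- and 1.34-fold lower of 26 (4 lower and 1 higher adjusted over the list alone). Their adjusted p was 0.245 and 0.329 with an estimated correlation. The cholesterol list rose with 1 of 20 called, Pmvk, 1.28-fold higher, and 5 adjusted over the list alone, and the cDC1 list rose with 4 of 29 higher and 1 lower (8 and 2 adjusted over the list alone), among them Irf8 and Cadm1, 1.43- and 1.48-fold higher. Each of these lists had an adjusted p = 0.329 with an estimated correlation. The lists of MHC class I presentation and pDC markers rose with 0 of 17 and 0 of 20 called, 0 and 0 adjusted over the list alone, and an adjusted p = 0.399 and 0.361 with an estimated correlation. Of the ESAM-low cDC2 genes, which did not pass as a list (adjusted p = 0.103), Fcgr3, Lyz2 and Csf3r were 1.79-, 1.68- and 1.60-fold higher and Cd209a 1.98-fold lower. The B cell, T cell, NK cell and neutrophil lists did not pass (adjusted p 0.828, 0.959, 0.732 and 0.828).

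The count of 291 became 72, 72, 73 and 164 without replicates 1 and 2 of WT cDC2 and replicates 1 and 2 of Flt3L KO cDC2, and 16 of the 53 called genes named by the rule kept their calls each time, among them C1qa, C1qb, C1qc, Vcam1, Mertk, Clec4e, Cd36, Cd101 and Cd209a but not Kcnma1. With a trended, robust prior the count was 487.

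**Figure D3:**
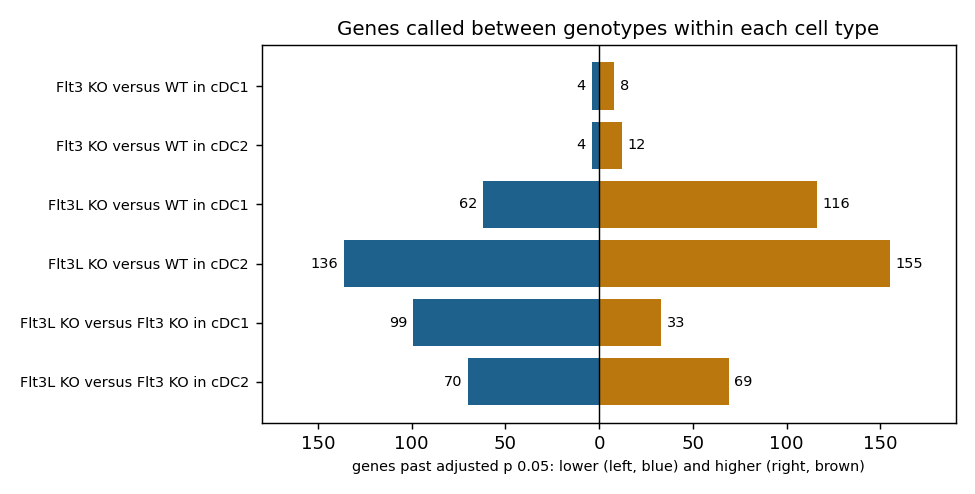
Number of genes past adjusted p 0.05 in each comparison of genotypes within a cell type; bars to the left count genes lower and bars to the right genes higher in the genotype named first. The bars run from 4 genes lower in either Flt3 KO comparison to 155 genes higher in Flt3L KO cDC2.

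Averaged over cell types, again with cDC1 and cDC2 arrays taken as independent, 449 genes differed between Flt3L KO and WT, 250 higher and 199 lower. Kcnma1, Mid1, Nnt, AI506816, Vcam1, Oasl1, Fscn1 and Lgals3bp were among those that rose, and Timd4, Fam71a, Fam135a, Dpep2, Olfml3, Cd180, Lsmem1 and Btbd19 among those that fell, from -0.78 for Timd4 to -0.52 for Btbd19 on the log2 scale. Without single arrays the count was 160 and 152 (WT cDC2 replicates 1 and 2), 158 and 260 (Flt3L KO cDC1 replicates 1 and 2) and 144 (Flt3L KO cDC2 replicate 1), and the other arrays moved it by less than 1.5 times. It was 779 with a trended, robust prior and 283 when only these arrays were fitted.

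Whether a knockout acted differently in cDC2 and cDC1 was tested as an interaction. For Flt3 KO, limma called 0 genes and camera 0 lists, with 1342 at an unadjusted p under 0.05; a trended, robust prior gave 5, and leaving out WT cDC1 replicate 2 gave 170 and Flt3 KO cDC1 replicate 2 gave 1. For Flt3L KO it called 74 genes, 37 with a higher and 37 with a lower change in cDC2. C1qa and C1qb rose more in cDC2 than in cDC1, by 2.14 ± 0.21 and 2.04 ± 0.26 (SE) on the log2 scale (adjusted p = 0.00136 and 0.00626), and in cDC1 they changed by 0.07 and -0.06. Cd36 fell by 0.52 in cDC1 and rose by 1.30 in cDC2. The macrophage list passed with the preset correlation and with an estimated one (adjusted p = 0.0322), with 4 of 18 members higher and 0 lower and 8 and 1 adjusted over the list alone; 9 other lists passed, each lost with an estimated correlation, where the smallest adjusted p was 0.0906. The count of 74 became 484, 20, 25, 25 and 34 without WT cDC1 replicate 2, WT cDC2 replicates 1 and 2, Flt3L KO cDC1 replicate 1 and Flt3L KO cDC2 replicate 1, and was 208 with a trended, robust prior, 118 with a share of 0.5 of the dimmest genes left out and 37 when only these arrays were fitted.

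The knockouts were also compared directly; the WT arrays enter these differences only through the variance of the joint fit. In cDC1, Mid1 was 8.11-fold higher in Flt3L KO than in Flt3 KO (adjusted p = 4.8e-05), Flt3 6.71-fold and Lnx2 2.90-fold. Ndrg1, AI506816, the vitamin D receptor gene Vdr, Ifi27l2a and the fatty acid receptor gene Ffar4 were 1.83-, 1.81-, 1.65-, 1.64- and 1.61-fold higher. Of these higher genes, Mid1, Flt3, Lnx2 and Ndrg1 kept their calls with each array left out, and the others did not. Clec4b2 was 4.54-fold lower, Adgrl3 2.39-fold, Fcrla 2.36-fold, Hpgd 2.33-fold and Adgrf5 2.31-fold, and the chemokines Cxcl2 and Ccl3 were 2.25- and 2.08-fold lower. Ms4a1, which encodes CD20, was 2.12-fold lower. All of these lower genes but Ccl3 kept their calls with each array left out. In all, 132 genes passed, 33 higher and 99 lower in Flt3L KO. The chemokine list fell, with 4 of 23 lower (7 adjusted over the list alone), as did the immediate early list, with 2 of 26 lower (10 lower and 1 higher adjusted over the list alone). The list of receptor tyrosine kinase and STAT5 response genes fell, with Egr2, Dusp6 and Phlda1 1.49-, 1.77- and 1.36-fold lower of 29 (6 lower and 1 higher adjusted over the list alone). Each of these lists had an adjusted p = 0.568 with an estimated correlation. The cDC1 list fell with 1 of 29 lower, Cd36 (3 lower and 1 higher adjusted over the list alone), and the oxidative phosphorylation list fell with 0 of 31 called and 0 adjusted over the list alone; their adjusted p was 0.568 and 0.623 with an estimated correlation. The interferon-stimulated list was higher, with 1 of 26 called and 6 adjusted over the list alone, and its adjusted p = 0.623 with an estimated correlation. The count of 132 became 20, 16, 17 and 63 without replicates 1 and 2 of Flt3 KO cDC1 and replicates 1 and 2 of Flt3L KO cDC1. It was 401 with a trended, robust prior, 267 with a share of 0.5 of the dimmest genes left out, 86 with no filter and 78 when only these arrays were fitted.

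In cDC2, Mid1 was 5.50-fold higher in Flt3L KO than in Flt3 KO (adjusted p = 0.000484), Flt3 4.55-fold and Clec4e 3.33-fold. C1qa, C1qb and C1qc were 2.10-, 2.32- and 2.28-fold higher, Fcgr4 2.46-fold, Lnx2 2.28-fold, Smpdl3b 2.17-fold and Vcam1 1.59-fold. Of these higher genes, Mid1, Flt3, Clec4e, Lnx2 and Vcam1 kept their calls with each array left out, and the others did not. H2-M2 was 2.35-fold lower, the transporter gene Abca9 2.17-fold, Mmp12 2.15-fold, Cd209a 1.98-fold and Clec9a 1.63-fold. Pnma1, Lrrc32 and Adgrl3 were 1.77-, 1.77- and 1.65-fold lower. Among these lower genes, only Abca9 kept its call with each array left out. In all, 139 genes passed, 69 higher and 70 lower. The cell cycle list was higher, with 2 of 35 called, Ube2c and Ccnb2, and 20 adjusted over the list alone, and the interferon-stimulated list was higher, with 3 of 26 called, Oasl1, Ifi27l2a and Mx2, and 14 adjusted over the list alone. Their adjusted p was 0.293 and 0.244 with an estimated correlation. The replicates of Flt3 KO cDC2 and of Flt3L KO cDC2 each differed by a median of 0.28 over the cell cycle list, against a difference of 0.34 between the groups, and the replicates of Flt3L KO cDC2 differed by 0.33 over the interferon list, against 0.42 between the groups. The macrophage list (5 of 18 higher; 8 higher and 2 lower adjusted over the list alone) and the monocyte list (3 of 13 higher; 5 adjusted over the list alone) were higher, and the cDC2 list (3 of 28 lower; 10 adjusted over the list alone) and the ESAM-low list (1 of 17 lower; 7 lower and 2 higher adjusted over the list alone) were lower. Their adjusted p was 0.107, 0.244, 0.107 and 0.244 with an estimated correlation. The immediate early list (2 of 26 lower; 3 adjusted over the list alone) and the pan-cDC list (1 of 20 lower, and Flt3 higher; 5 and 1 adjusted over the list alone) were lower, each with an adjusted p = 0.244 with an estimated correlation. The lists of MHC class II (0 of 13; 3 lower adjusted over the list alone) and class I presentation (0 of 17; 0 adjusted over the list alone) were lower and higher, with adjusted p = 0.293 and 0.409 with an estimated correlation. The count of 139 became 50, 21 and 8 without Flt3 KO cDC2 replicates 1 and 2 and Flt3L KO cDC2 replicate 1, and 268 with a trended, robust prior. Averaged over cell types, 435 genes differed, 126 higher and 309 lower, among them the interferon regulator Irf7, with a log2 difference of 0.58, and Timd4, 1.38-fold lower. That count became 119, 116, 192, 133, 121, 252 and 115 without Flt3 KO cDC1 replicates 1 and 2, Flt3 KO cDC2 replicates 1 and 2, Flt3L KO cDC1 replicates 1 and 2 and Flt3L KO cDC2 replicate 1, and 773 with a trended, robust prior.

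The effects of the knockouts were set beside each other within a cell type. In cDC1, Adam11, Fcer1g, Lpp and Nnt rose in both knockouts, 4 genes where 0.0621 are expected of independent lists, and 0 genes fell in both. In cDC2, C1qa, Fabp5, Lyz2, Maged1, Mmp14, Ms4a7, Nnt, Osm and Vcam1 rose in both, 9 genes where 0.124 are expected, and Bank1 fell in both, where 0.0364 are expected. Unchanged groups simulated against shared WT arrays gave a mean of 0 shared calls, but also a mean of 0 calls per comparison, so they set no baseline for shared calls. Across all tested genes, which are not independent replicates, the correlation of the log2 changes was 0.455 in cDC1 and 0.451 in cDC2, and 0.5 in the simulation. The covariance was 0.0116 in cDC1 and 0.00988 in cDC2, against 0.0052 in the simulation, which used the spread pooled over all groups. The difference between the WT replicates of each cell type puts the part due to shared WT arrays at 0.011 in cDC1 and 0.0043 in cDC2. By that estimate, which rests on 2 arrays each, nearly all of the covariance in cDC1 is what the WT arrays alone would give, and 0.00558 is left in cDC2. With 2 WT arrays per cell type, the knockouts could not each be given 2 WT arrays of their own, so part of the shared calls may come from the shared WT arrays. Within a genotype, Nnt rose and Flt3 and Lnx2 fell in both cell types of Flt3 KO, and 11 genes rose, 12 fell and 3 moved in opposite directions in both cell types of Flt3L KO, where 1.2 rises and 0.564 falls are expected of independent lists.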

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

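Tests chosen only after the result was seen are those on the genes near Flt3, on FLT3 signalling as the source of the Nnt change, and on the purity of the sort; the tests on Wdfy1 and Entpd4, on the regions around Nnt and Flt3l, and on red pulp macrophage genes were chosen before. The purity test and the signalling tests of the genes near Flt3 replaced first versions that left the question undecided.

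A difference between the cell types in the effect of Flt3L loss singled out 74 genes by the interaction test. Among them the change in cDC2 exceeded that in cDC1, on the log2 scale, by 2.34 for Clec4e, 2.14 for C1qa, 2.04 for C1qb, 1.82 for Cd36, 1.74 for Cd300e, 1.55 for Clec4b2, 1.54 for Pparg and 1.52 for Smpdl3b. Clec4e lay under the lower quartiles on the WT and Flt3L KO arrays of cDC1, so its change there is poorly measured. The change was lower in cDC2, with differences of -1.19 for Cd209a, -1.13 for Cd69, -1.07 for Abca9, -0.94 for Cd101, -0.90 for Adam11, -0.86 for Stat4, -0.84 for Gpr141 and -0.84 for Cdon. Of the genes named here, Clec4e, C1qa, C1qb, Cd36, Abca9, Cd101 and Adam11 kept their calls with each array left out, and the others did not. Probe sets without a single gene symbol, which no comparison of genes uses, also held signal: of 8388 tested, 21 were called in Flt3L KO cDC1 and 36 in Flt3L KO cDC2 against WT.

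Macrophage-type genes rose in Flt3L KO cDC2, with a median log2 change of 1.99 for C1qa, C1qb and C1qc. Markers of B cells, T cells, NK cells and neutrophils showed no rise of that size as lists. The highest upper quartile of the changes among these lists was 0.2114, under the bound set for the purity test. That bound was chosen after the result was seen, so the test does not decide whether a small share of such cells was present. Monocytes among the sorted cDC2 were not tested, and the monocyte list rose in Flt3L KO cDC2. Splenic macrophages among the sorted cDC2 stay open: of Spic, Cd5l and Slc40a1 only Spic passed the filter on dim genes, and its change was 0.4076 times the C1q median, between the bounds set for either outcome; the mean intensity of Slc40a1 went from 19.2 in WT to 38.5 and that of Cd5l from 19.6 to 26.1. Timd4, also a macrophage gene, fell in both cell types, and the gates of the sort are not given in the sources used here. A change in the cDC2 themselves without FLT3L may also explain the rise, and was not tested apart from these.

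Genes near Flt3 changed in Flt3 KO: Lnx2, Polr1d, Hsph1, Rfc3 and Zdhhc4 were 5 called among 70 neighbours tested, where 0.169 are expected, with a Fisher exact p of 6.66e-07. This is what an effect limited to the region of the targeted allele predicts, whether from the allele or from flanking DNA of another strain, which these values do not separate. Loss of FLT3 signalling is argued against for Lnx2, with log2 changes averaged over cell types of -1.10 in Flt3 KO and 0.26 in Flt3L KO. For Lnx2 and Polr1d the larger ratio of the averaged Flt3L KO change to the Flt3 KO change was 0.1726, that of Polr1d. In cDC1 alone, Polr1d had a mean log2 value of 10.21 in WT, 9.56 in Flt3 KO and 10.01 in Flt3L KO. A shared part of its fall therefore stays open in cDC1. For Hsph1, Rfc3 and Zdhhc4 loss of FLT3 signalling stays open, with a median ratio of 0.3936. Hsph1 also fell in Flt3L KO (-0.41, adjusted p = 0.0202 in limma), which an effect limited to the region of the Flt3 allele does not predict. The knockouts differed in limma for Rfc3 (adjusted p = 0.0216) but not for Hsph1 and Zdhhc4 (adjusted p = 0.0832 and 0.0741). Around Flt3l in Flt3L KO the same test of a region found 0 of 100 neighbours called, with a Fisher exact p of 1.

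Nnt rose in both knockouts. A substrain difference between WT and knockout mice predicts changes of Wdfy1 and Entpd4 too, and 0 of their 4 tests averaged over cell types passed, but it stays open: the averages hide a log2 change of -0.43 ± 0.12 (SE, adjusted p = 0.106) for Entpd4 in Flt3L KO cDC2, beyond the bound set for the averages. Ide, another gene held to differ between substrains and chosen after its values were seen, rose in both Flt3 KO and Flt3L KO (0.45 and 0.44, adjusted p = 0.0298 and 0.0122), while Mid1 rose in Flt3L KO only (2.14, adjusted p = 3.26e-05; -0.60, adjusted p = 0.213 in Flt3 KO). A response to loss of FLT3 signalling stays open, since the smaller of the Nnt changes was 1.347 and a background difference gives the same pattern. A region around Nnt differing between WT and knockouts stays open too, with a larger Fisher exact p of 1, since only 0.145 and 1.8 called neighbours were expected in Flt3 KO and Flt3L KO.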

How the results depend on the processing

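The block of crossed replicate numbers was chosen only after the data were seen; all other settings were planned. Of 830 values of named genes under 9943 alternatives, 9079 stayed on their side of the threshold, 674 lost the call, 190 gained it and 0 reversed. Counts of genes between cDC1 and cDC2 stayed within 1.5 times under each setting. The cause was not tested where a count moved. With a trended, robust prior, the counts were 35, 36, 545, 487, 401 and 268 (Flt3 KO cDC1 and cDC2, Flt3L KO cDC1 and cDC2, Flt3L KO against Flt3 KO in cDC1 and cDC2), 67, 779 and 773 for the averages and 5 and 208 for the interactions. With a share of 0.5 of the dimmest genes left out, so that fewer genes were tested, they were 22 (Flt3 KO cDC1), 9 (Flt3 KO cDC2), 363 (Flt3L KO cDC1), 267 (between knockouts, cDC1) and 118 (Flt3L KO interaction), and fixed lists that passed were 11 (WT cell types), 4 (Flt3 KO cDC1) and 5 (between knockouts, cDC2). With no dim filter they were 10 (Flt3 KO cDC2), 98 (Flt3L KO cDC1) and 86 (between knockouts, cDC1). With only the arrays compared, which leaves fewer residual degrees of freedom, they were 3 (Flt3 KO cDC1), 6 (Flt3L KO cDC1), 78 (between knockouts, cDC1), 22 and 283 (averages of Flt3 KO and Flt3L KO) and 37 (Flt3L KO interaction). The mean of probe sets gave 7 (Flt3 KO cDC1), and the replicate block 118 (Flt3L KO cDC1). Quantile normalization gave 4 lists in Flt3 KO cDC1 and 2 between knockouts in cDC1. With an estimated correlation the lists numbered 5 (WT cell types), 0, 1, 0 and 0 (Flt3 KO cDC1 and cDC2, Flt3L KO cDC1 and cDC2) and 0 and 0 (between knockouts, cDC1 and cDC2).

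With each array left out in turn, counts of genes ranged from 3 to 1132 (Flt3 KO cDC1), 2 to 6 (Flt3 KO cDC2), 25 to 606 (Flt3L KO cDC1), 72 to 164 (Flt3L KO cDC2), 16 to 63 and 8 to 130 (between knockouts, cDC1 and cDC2), 9 to 219, 144 to 591 and 115 to 346 (averages of Flt3 KO, Flt3L KO and between knockouts) and 0 to 170 and 20 to 484 (interactions of Flt3 KO and Flt3L KO). Lists that passed ranged from 4 to 7 (Flt3 KO cDC1), 3 to 9 (Flt3L KO cDC1) and 3 to 6 (between knockouts, cDC1). The highest counts among comparisons with WT cDC1 came without its replicate 2, which leaves replicate 1, the array that stood apart, except in the Flt3L KO average, where it came without replicate 1.

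Equal replicate numbers within a genotype correlated at 0.16, 0.09 and 0.15 (WT, Flt3 KO and Flt3L KO), and at -0.17, -0.13 and -0.10 between WT cDC1 and Flt3 KO cDC1, WT cDC1 and Flt3L KO cDC1, and WT cDC2 and Flt3 KO cDC2; a crossed replicate block for these last 3 gave 20, 281 and 18 genes. Of all other pairs of groups the values ran from -0.20 (WT cDC1 and Flt3L KO cDC2) to 0.17 (Flt3 KO cDC2 and Flt3L KO cDC2). Arrays limit these results through background, which may understate the fold changes of dim genes.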

Other observations

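The test of small RNA genes, and the restriction of the splits to those that keep cell types or genotypes even, were chosen only after the result was seen.

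Small nucleolar and microRNA genes held 14 called as lower and 1 as higher of 189 tested in Flt3L KO cDC2 against WT, and 11 as lower and 0 as higher against Flt3 KO. In Flt3L KO cDC1, 4 were called as higher and 0 as lower against WT, and 3 and 0 against Flt3 KO. In Flt3L KO cDC2 against WT the camera p was 0.00205 with the preset correlation and 0.191 with an estimated one. A loss shared by the whole class there is argued against, since the share with a lower value was 0.5344; a loss in part of it stays open.

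Other splits of the arrays were fitted with cell type, or genotype for the comparison of cell types, as a further term, a smaller model than that of the reported counts. With 2 arrays of each cell type on either side there are 18 splits, too few for a share under 0.05: only the real one, 1 of 18, gave as many genes for Flt3 KO against WT (17, at most 0 in other splits), Flt3L KO against WT (126, at most 1) and Flt3L KO against Flt3 KO (348, at most 1). For cDC1 against cDC2, with 2 arrays of each genotype on either side, 1 of 100 drawn splits gave as many (7463, at most 0 in others). Each of the other splits put both cell types on either side, so the large cell type difference entered their residual spread. Few calls were bound to follow, so these splits do not decide whether chance gave the count.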
